A study of Mus musculus with 6 samples.

How the data were processed

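Messenger RNA was measured in 6 libraries of cultured mouse hepatic stellate cells, 3 from S100a16+/- mice and 3 from WT mice, each after 7 days in culture. Per the labels' protocols, RNA with an integrity number above 7 was selected on oligo(dT) beads, made into strand-marked libraries by the dUTP method with adapters that carried unique molecular identifiers, and sequenced from both ends on a NovaSeq. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, but the role and order of each are not given in the sources used here.

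The values came from a single table of 55401 Ensembl mouse genes with symbols, coordinates and annotation terms. Per the file headers, the authors deposited a count and an FPKM value for each gene and library. The deposited counts were whole numbers with no scaling between libraries. Whether a count is a read or a fragment, whether molecular identifiers were collapsed, and whether counting used the strand are not given in the sources used here. The deposited FPKM values were scaled by the authors to gene length and library size, and a gene with a count of 0 carried a placeholder FPKM of 0.0001. The genome build is not given in the sources used here. Of the gene identifiers, 55141 (99.5%) were in GENCODE M21, and 51957 of these (94.2%) had the same coordinates as in that annotation of GRCm38. Coordinates are printed as the table gives them.

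Library totals ran from 61979103 to 76291481 counts. The plan fixed before the data were examined assumed FPKM alone and a limma fit, and named edgeR on counts if counts were found. Counts were found, so edgeR was the main test and the limma fit became an alternative. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested. Counts were scaled by TMM and fitted with edgeR 4.0.16 quasi-likelihood (R 4.3.3), with genotype as the only term and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05 with no fold threshold. Log2 changes are S100a16+/- over WT, and each SE is the size of the log2 change divided by the square root of the F statistic. For S100a16 and Cxcr4 the FPKM values were also compared by an exact two-sided permutation test.

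The 38 gene lists were fixed before the data were examined and cover matrix and contractile genes, signalling and stress pathways, metabolism, the cell cycle and markers of other liver cell types. Lists with at least 5 tested members were compared with all other tested genes by camera in limma 3.58.1 on log2(FPKM + 1), two-sided, with its preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The GO and KEGG annotation deposited with the genes was tested in the same way for terms of 15 to 300 tested genes, adjusted within GO and within KEGG. List medians per library are log2 ratios of CPM to the WT mean. Principal components and correlations across genes used log2(FPKM + 1).

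The rule for named genes was fixed before the data were examined. It took S100a16 and Cxcr4, and the 12 largest rises and 12 largest falls in log2(FPKM + 1) among called genes with non-overlapping groups, a mean FPKM of at least 1 and a symbol that is not a predicted gene or pseudogene. It also took up to 4 called members of each list, or the 2 with the smallest p where none was called, the 2 most abundant markers of each cell type, and 9 genes of stellate cell activation. Sex-linked genes were named after their values were seen. Named genes were checked for overlap with other annotated genes. Counts of copies were looked up for Rpl29 only, by name and description, and the other named genes were not checked for copies.

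The alternatives covered pseudocounts of 0.1 and 5, filters, scalings, array weights, the replicate number as a block, each library left out in turn, thresholds and other set tests. A DESeq2 1.42.0 fit, library totals without TMM and camera on counts were chosen after the data were seen. The fit without S100a16+/- replicate 3 was planned as a left-out library, and its counts of genes, list members and terms were set beside the main ones after its values were seen. On data simulated from the 6 libraries, the edgeR step recovered 47% of genes changed 2-fold and 84% of those changed 4-fold, and 7.09% of its calls were false. With the design without S100a16+/- replicate 3 these were 80%, 93% and 8.95%. The simulation drew each gene on its own with the same dispersion in every library. It held no outlying library and no correlation between genes, so these rates may not hold for the real libraries. Nothing in the table was left out apart from genes below the FPKM minimum, and no reads were used here.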

Results

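Hepatic stellate cells, the pericytes that turn into collagen-producing myofibroblasts in culture, came from WT mice and from mice heterozygous for S100a16 (S100a16+/-). Messenger RNA was sequenced from 3 libraries of each genotype. The S100a16+/- libraries, replicates 1 to 3, held 70896338, 70064318 and 61979103 counts, and the WT libraries held 65880770, 76291481 and 72473992. The comparison asks which genes differ in these stellate cell cultures when S100a16 is reduced, and whether the chemokine receptor gene Cxcr4 is among them. The cultures also held transcripts of other liver cells. In WT the macrophage gene Marco had a mean FPKM of 1197 and the endothelial gene Cdh5 of 661. A change therefore need not lie in the stellate cells. The labels do not say whether the libraries are separate animals, so the p-values measure the spread between these samples.

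S100a16 encodes an EF-hand calcium-binding protein. The gene (ENSMUSG00000074457, chromosome 3, 90537254 to 90543151, plus strand) overlapped no other annotated gene. Its FPKM was 18.0, 17.7 and 30.0 in the S100a16+/- libraries and 57.7, 58.8 and 56.8 in the WT libraries. The means were 21.9 ± 7.02 (SD, n = 3) and 57.8 ± 1.02 (SD, n = 3), so the S100a16+/- mean was 38.0% of the WT mean (exact permutation p = 0.1, two-sided). A p of 0.1 is the smallest that the 10 splits of 3 against 3 libraries allow. S100a16+/- replicates 1, 2 and 3 stood at 31.2%, 30.7% and 52.0% of the WT mean. What part the mix of cells has in these levels was not tested. In the fit to all genes S100a16 fell by 1.35 on the log2 scale (SE 0.21, edgeR adjusted p = 0.0313). Its log2 change was -1.63 without S100a16+/- replicate 3 (edgeR adjusted p = 4.04e-05). Leaving out any of the other 5 libraries ended the call: the log2 change was -1.23 without S100a16+/- replicate 1, -1.22 without S100a16+/- replicate 2, and -1.35, -1.35 and -1.37 without WT replicates 1, 2 and 3, with edgeR adjusted p from 0.110 to 0.146. With no filter on low values the log2 change was -1.36 (edgeR adjusted p = 0.0516).

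Cxcr4, the receptor for the chemokine CXCL12 (ENSMUSG00000045382, chromosome 1, 128588199 to 128592293, minus strand), was lower in each S100a16+/- library than in each WT library. Its FPKM was 14.9, 17.3 and 52.4 in the S100a16+/- libraries and 69.4, 64.9 and 60.2 in the WT libraries. The means were 28.2 ± 21.03 (SD, n = 3) and 64.8 ± 4.61 (SD, n = 3; exact permutation p = 0.1, two-sided). S100a16+/- replicates 1 and 2 stood at 22.9% and 26.6% of the WT mean and replicate 3 at 80.9%. The log2 change of -1.16 (SE 0.49) did not pass the test over all 6 libraries (edgeR adjusted p = 0.241). It passed without S100a16+/- replicate 3, at -1.95 (edgeR adjusted p = 0.000173). That fit rests on S100a16+/- replicates 1 and 2, which may come from the same animal, so its p may not measure the spread between animals.

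S100a16+/- replicate 3 stood apart from the other 5 libraries. Across genes, its Pearson correlation with S100a16+/- replicates 1 and 2 was 0.930 and 0.929, against 0.987 between those libraries, 0.981 to 0.985 among the WT libraries and 0.946 to 0.949 between it and WT. It was the library with female-type expression: the X-inactivation transcript Xist had an FPKM of 32.2 in it and at most 0.0323 in the others, and the Y-linked gene Ddx3y 0.0102 against 12.1 to 15.8. It also differed in genes of liver cell types. The hepatocyte gene Alb had an FPKM of 242 in it, 4.81 and 5.52 in S100a16+/- replicates 1 and 2, and 42.9 to 64.6 in the WT libraries. Acta2, the smooth-muscle actin of myofibroblasts, had an FPKM of 48.0 in it, against 489 and 470 in S100a16+/- replicates 1 and 2 and 388 to 437 in the WT libraries.

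**Figure D1:**
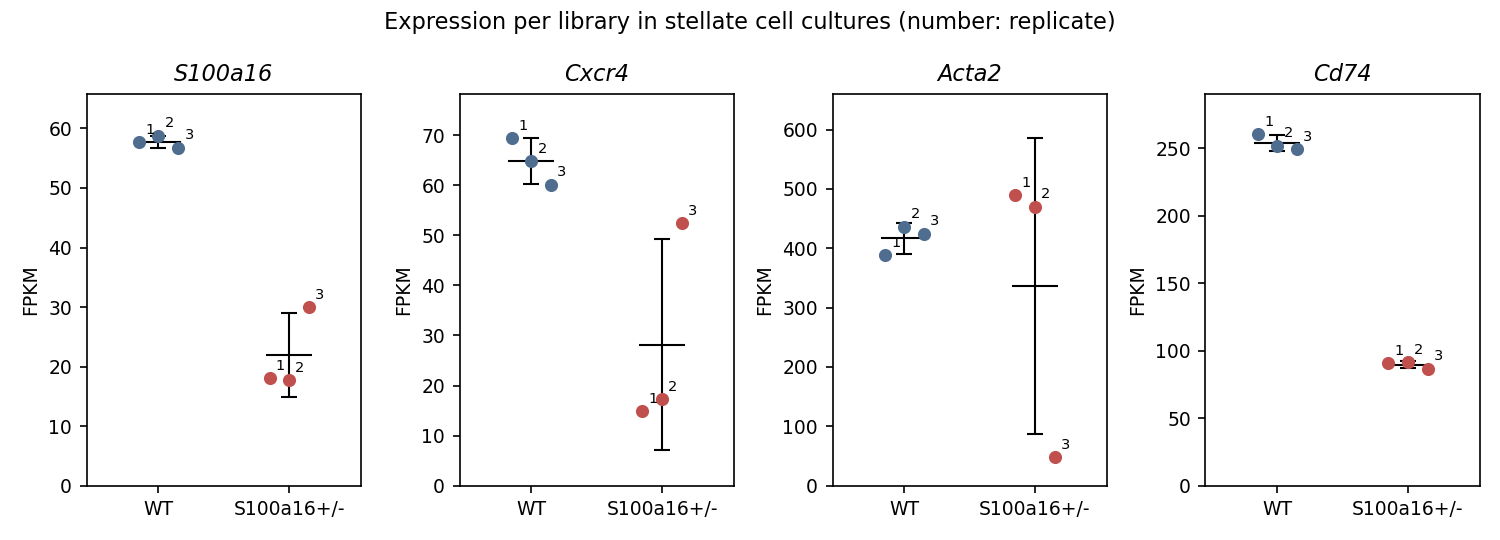
FPKM of S100a16, Cxcr4, Acta2 and Cd74 in each of the 3 S100a16+/- and 3 WT libraries, a point per library, with the mean and SD of each group. S100a16 and Cd74 lie lower in all 3 S100a16+/- libraries, while Cxcr4 at 52.4 and Acta2 at 48.0 set S100a16+/- replicate 3 apart from the other 2 of its group.

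Of 12766 genes tested, 364 rose and 206 fell in the S100a16+/- libraries (edgeR quasi-likelihood, Benjamini-Hochberg). All 570 had non-overlapping groups, as did 31.4% of the tested genes, where chance gives 10%. With S100a16+/- replicate 3 left out, 1990 genes were higher and 2076 lower of 12601 tested, and these held 538 of the 570 in the same direction. The 538 were 332 of the 364 higher calls and all 206 lower calls. That fit still needed 3 libraries at the FPKM minimum, so genes reaching it only in S100a16+/- libraries were not tested. Without S100a16+/- replicates 1 or 2, 46 and 32 genes were higher and 22 and 15 lower. Without WT replicates 1, 2 or 3, 30, 23 and 20 were higher and 6, 7 and 5 lower. The share of calls that were higher was 63.9%. It was 52.8% (282 higher, 252 lower) with library totals alone, 45.3% (228 and 275) with TPM and 51.3% (260 and 247) with limma on log2(FPKM + 1).

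The largest rises included Acod1 and Epo. Acod1, which makes itaconate in activated macrophages, rose by a log2 change of 3.64 (SE 0.37, edgeR adjusted p = 0.0122), from a mean FPKM of 6.39 ± 0.371 to 76.6 ± 31.6 (SD, n = 3 each). The chemokine gene Ccl4 rose by 2.49 (SE 0.11, edgeR adjusted p = 0.00133), the formyl peptide receptor gene Fpr2 by 2.20 (SE 0.07, edgeR adjusted p = 0.000570) and the C-type lectin gene Clec4d by 2.13 (SE 0.17, edgeR adjusted p = 0.00622). S100a8, a neutrophil and monocyte calcium-binding protein gene, rose by 3.28 (SE 0.56, edgeR adjusted p = 0.0386), and Spp1, which encodes osteopontin, by 2.41 (SE 0.43, edgeR adjusted p = 0.0412). The B-cell chemokine gene Cxcl13 rose by 2.14 and the antiviral gene Oas3 by 3.04 (edgeR adjusted p = 0.0177 and 0.00303). Cyp26b1, which breaks down retinoic acid, rose by 3.09 (edgeR adjusted p = 0.0499), and its log2 change was 2.15 without S100a16+/- replicate 3. S100a8 moved to 3.87 without WT replicate 2. Epo, the erythropoietin gene, had 407, 148 and 103 counts in the S100a16+/- libraries and 0 in the WT libraries. That was at least 241-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.0383). Epo was not tested without S100a16+/- replicate 3, because the filter still needed 3 libraries at an FPKM of 1. Its FPKM was 6.04 and 2.22 in S100a16+/- replicates 1 and 2. With a WT library left out it was tested and not called.

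The largest falls included the dendritic and macrophage lectin genes Cd209f and Cd209g, at log2 changes of -2.54 (SE 0.08, edgeR adjusted p = 0.000570) and -2.84 (SE 0.11, edgeR adjusted p = 0.00102). Col15a1, a basement membrane collagen gene, fell by 2.96 (SE 0.36, edgeR adjusted p = 0.0195), from a mean FPKM of 15.8 ± 0.683 to 1.96 ± 0.824 (SD, n = 3 each). Apol7c fell by 2.55, the neurotrophic receptor gene Gfra2 by 2.50 and the toll-like receptor gene Tlr12 by 1.83 (edgeR adjusted p = 0.00559, 0.00399 and 0.00622). Hpgd, which inactivates prostaglandins, fell by 1.60 and the sulfotransferase gene Sult1a1 by 2.20 (edgeR adjusted p = 0.0290 and 0.0394). Rpl29 and Bcl2a1d also rose, by 5.17 and 2.33 (edgeR adjusted p = 0.00440 and 0.0407), but both have near-identical copies. Reads moving to Rpl29 from its copies would lower these, but the copy Gm8995 had 6544, 7275 and 6296 counts in the S100a16+/- libraries against 3226, 3538 and 3087 in the WT libraries, and the others found by name had at most 44 in any library. The counts of Rpl29 and Bcl2a1d stay uncertain, as are those of the 10 named genes that overlap a neighbour with at least 10% of their counts: Epo, Sult1a1, Rtp4, Mcm7, Pfkp, Ciita, Timp1, Glb1, Ndufa2 and Ftl1. Of 65 called named genes with a value in each left-out setting, 10 passed in all 6: Ccl4, Cd209f, Cd209g, Cd74, Fabp5, Fpr2, Oas1a, Oas3, Rpl29 and Saa3.

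**Figure D2:**
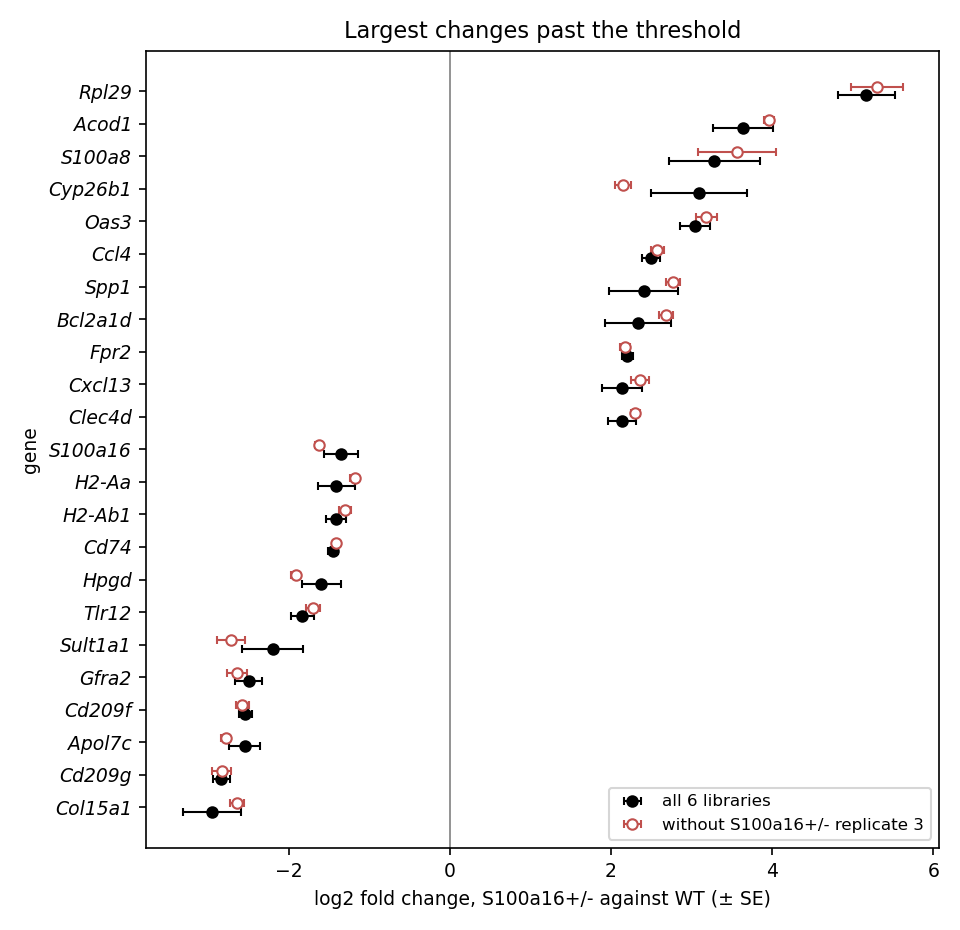
Log2 change, S100a16+/- over WT, with its SE (horizontal bars) for 23 of the genes with the largest changes, from edgeR fits to all 6 libraries and without S100a16+/- replicate 3. Epo, with no WT count, is left out, and all 23 genes keep their direction without that library, where their non-overlapping groups leave little room to reverse.

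Genes of inflammation and antiviral defence were among those that rose. In S100a16+/- replicates 1 to 3 the macrophage markers also had medians above 0, of 0.65, 0.74 and 0.23. What part macrophages have in these rises was not tested. Among chemokines and cytokines, 8 of 20 tested genes rose, and 11 rose and 1 fell adjusted over the list alone; beside Ccl4 and Cxcl13 they included Ccl3, at a log2 change of 1.72, and the interleukin gene Il1a, at 0.97 (edgeR adjusted p = 0.00559 and 0.00865). The list was higher by camera (adjusted p = 1.57e-07; adjusted p = 0.320 with an estimated correlation), and its median was 1.07, 0.88 and 0.91 in S100a16+/- replicates 1 to 3. Of the interferon-response genes 8 of 33 rose, and 24 adjusted over the list alone, including Oas1a at 1.10, Oasl2 at 1.82 and Rtp4 at 1.60 (edgeR adjusted p = 0.00236, 0.00981 and 0.0228). This list was also higher by camera (adjusted p = 4.36e-15; adjusted p = 0.351 with an estimated correlation), and its median was 0.59 and 0.60 in S100a16+/- replicates 1 and 2 and 1.303 in replicate 3. Among targets of NF-kappa B, the transcription factor of inflammatory signalling, 5 of 20 rose, and 7 rose and 2 fell adjusted over the list alone. They included the mitochondrial superoxide dismutase gene Sod2 at 1.81 and the acute-phase gene Saa3 at 1.35 (edgeR adjusted p = 0.00586 and 0.00399), as well as Nfkbie at 1.05 and Ptgs2, the inducible cyclooxygenase gene, at 0.89 (edgeR adjusted p = 0.0177 for both). Its camera adjusted p was 0.00193 (adjusted p = 0.320 with an estimated correlation). Without S100a16+/- replicate 3 the counts were 13 higher and 2 lower for chemokines and cytokines, 24 and 1 for the interferon response and 9 and 4 for NF-kappa B targets, and all 3 lists were higher by camera (adjusted p = 6.32e-07, 1.30e-09 and 0.0462; adjusted p = 0.365, 0.439 and 0.473 with an estimated correlation).

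Some macrophage markers rose, and the class II antigen-presentation genes named here fell. Among markers of macrophages and Kupffer cells, the resident macrophages of the liver, 5 of 25 rose, and 12 adjusted over the list alone (camera adjusted p = 0.000700; adjusted p = 0.351 with an estimated correlation). The scavenger receptor genes Marco and Msr1 rose by 1.17 and 1.20 (edgeR adjusted p = 0.0376 and 0.0141), the lipopolysaccharide co-receptor gene Cd14 by 1.17 (edgeR adjusted p = 0.0271) and Cd5l by 0.91 (edgeR adjusted p = 0.0206). Macrophage transcripts were abundant in both genotypes: the lysozyme gene Lyz2 had a mean FPKM of 8249 ± 2450 in S100a16+/- and 4464 ± 115 in WT (SD, n = 3 each), without passing the test (log2 change 0.94, edgeR adjusted p = 0.101), although it passed without S100a16+/- replicate 3 (1.18, edgeR adjusted p = 0.000123). Of 16 antigen-presentation genes 4 rose and 5 fell, against 6 and 5 adjusted over the list alone. Those that fell serve class II presentation: the invariant chain gene Cd74 at -1.45 (89.7 ± 2.59 against 254 ± 5.75 FPKM, SD, n = 3 each), H2-Ab1 at -1.41, H2-Aa at -1.41, H2-Eb1 at -1.32 and their regulator Ciita at -2.38 (edgeR adjusted p = 0.00133, 0.00847, 0.0350, 0.00847 and 0.00470). Those that rose serve class I presentation, H2-D1 at 0.79, H2-T23 at 0.78, Tapbp at 0.61 and Tap2 at 0.55 (edgeR adjusted p = 0.0104, 0.0249, 0.0376 and 0.0246), and were named after their values were seen. With members moving both ways, the list's median was 0.43 and its mean -0.19, and camera put it on the higher side without a call (adjusted p = 0.698). The set test fry called it on the lower side (adjusted p = 0.0103), and quantile normalization and camera on counts put it there without a call (adjusted p = 0.960 and 0.868). Without S100a16+/- replicate 3, 15 macrophage markers were higher and 5 lower, and 7 antigen-presentation genes were higher and 5 lower.

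Some matrix genes fell, while the type I and III collagen genes and Acta2 did not pass the test over all 6 libraries. Of 36 fibrillar collagen and matrix genes 6 fell, and 6 adjusted over the list alone (camera adjusted p = 1.57e-07; adjusted p = 0.351 with an estimated correlation). They included the elastin gene Eln at -4.10, Col14a1 at -1.75 and the biglycan gene Bgn at -0.67, beside Col15a1 (edgeR adjusted p = 0.0132, 0.0213 and 0.0195). The list's median was -0.43 and -0.47 in S100a16+/- replicates 1 and 2 and -1.64 in replicate 3, and without replicate 3, 20 of its members were lower and 2 higher (camera adjusted p = 2.35e-05; adjusted p = 0.439 with an estimated correlation). In the same replicates 1 to 3 the endothelial markers had medians of -0.98, -1.03 and 0.20. Without replicate 3, 15 endothelial markers were lower and 1 higher, and what part endothelial cells have in the matrix change was not tested. The type I collagen genes Col1a1 and Col1a2 had log2 changes of -0.51 and -0.71 (edgeR adjusted p = 0.742 and 0.569), and Col3a1 -1.43 (edgeR adjusted p = 0.121). Leaving out S100a16+/- replicate 3 made these 0.00, -0.24 and -1.07, and only Col3a1 of the 3 passed (edgeR adjusted p = 0.00237). Of 19 contractile genes 1 fell, Pdlim7 at -0.62 (edgeR adjusted p = 0.0272), against 2 adjusted over the list alone (camera adjusted p = 0.0590; 0.0103 and 0.00659 without S100a16+/- replicate 1 or 2, and 0.0470 without WT replicate 1; adjusted p = 0.723 over all 6 with an estimated correlation). The list turned to the higher side, uncalled, without S100a16+/- replicate 3 (median 0.09, camera adjusted p = 0.468). Acta2 had a log2 change of -0.25 (edgeR adjusted p = 0.884) and of 0.27 without S100a16+/- replicate 3 (edgeR adjusted p = 0.0185), where 6 contractile genes were higher and 4 lower. Among matrix proteases and their inhibitors 3 of 24 rose, and 4 adjusted over the list alone: Mmp9 at 1.44, Mmp10 at 1.11 and Mmp14 at 0.47 (edgeR adjusted p = 0.0400, 0.0103 and 0.0198). That list's camera adjusted p was 0.0569, and without S100a16+/- replicate 3 it was 0.000149 with 13 higher and 2 lower (adjusted p = 0.723 and 0.365 with an estimated correlation). The inhibitor gene Timp1 had a log2 change of 0.00 (edgeR adjusted p = 0.996), and 0.43 without that library (edgeR adjusted p = 0.00386).

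Cell-cycle genes had a median below 0 in all 3 S100a16+/- libraries. Of 39 tested, 12 fell, and 24 adjusted over the list alone (camera adjusted p = 9.02e-11; adjusted p = 0.351 with an estimated correlation). The centromere genes Cenpa, Cenpf and Cenpe fell by 0.98, 0.84 and 0.60 and the replication helicase gene Mcm7 by 0.62 (edgeR adjusted p = 0.0120, 0.0198, 0.0198 and 0.0216). The list's median was -0.43, -0.55 and -0.61 in S100a16+/- replicates 1 to 3, and without replicate 3, 27 of its members were lower (camera adjusted p = 3.77e-06; adjusted p = 0.597 with an estimated correlation). Genes of the CXCR4 and CXCL12 axis were lower as a list (camera adjusted p = 0.0228; adjusted p = 0.332 with an estimated correlation). Of its 12 members 2 fell, Cd74 and the decoy receptor gene Ackr3 at -1.11 (edgeR adjusted p = 0.0118), and 4 adjusted over the list alone. Cd74 is also in the antigen-presentation list and Cxcr4 is itself a member, so this list is not independent of those results. Cxcl12 itself had a log2 change of -0.84 (edgeR adjusted p = 0.0824), and passed at -0.64 without S100a16+/- replicate 3 (edgeR adjusted p = 0.00572). Of its members 7 were lower and 2 higher without S100a16+/- replicate 3 (camera adjusted p = 0.0357; adjusted p = 0.439 with an estimated correlation). The list was not called among genes with a mean FPKM of at least 5 or by ranks (camera adjusted p = 0.191 and 0.0817). Of the p53 targets, genes switched on by the tumour suppressor p53, 1 rose and 1 fell among 30, also adjusted over the list alone: the death receptor gene Fas at 0.66 and the kinase gene Plk3 at -0.37 (edgeR adjusted p = 0.0367 and 0.0497; camera adjusted p = 0.662). The p53 gene Trp53 had a log2 change of -0.22 (edgeR adjusted p = 0.145), and passed at -0.28 without S100a16+/- replicate 3 (edgeR adjusted p = 0.00794). Among p53 targets 5 were higher and 8 lower without S100a16+/- replicate 3.

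**Figure D3:**
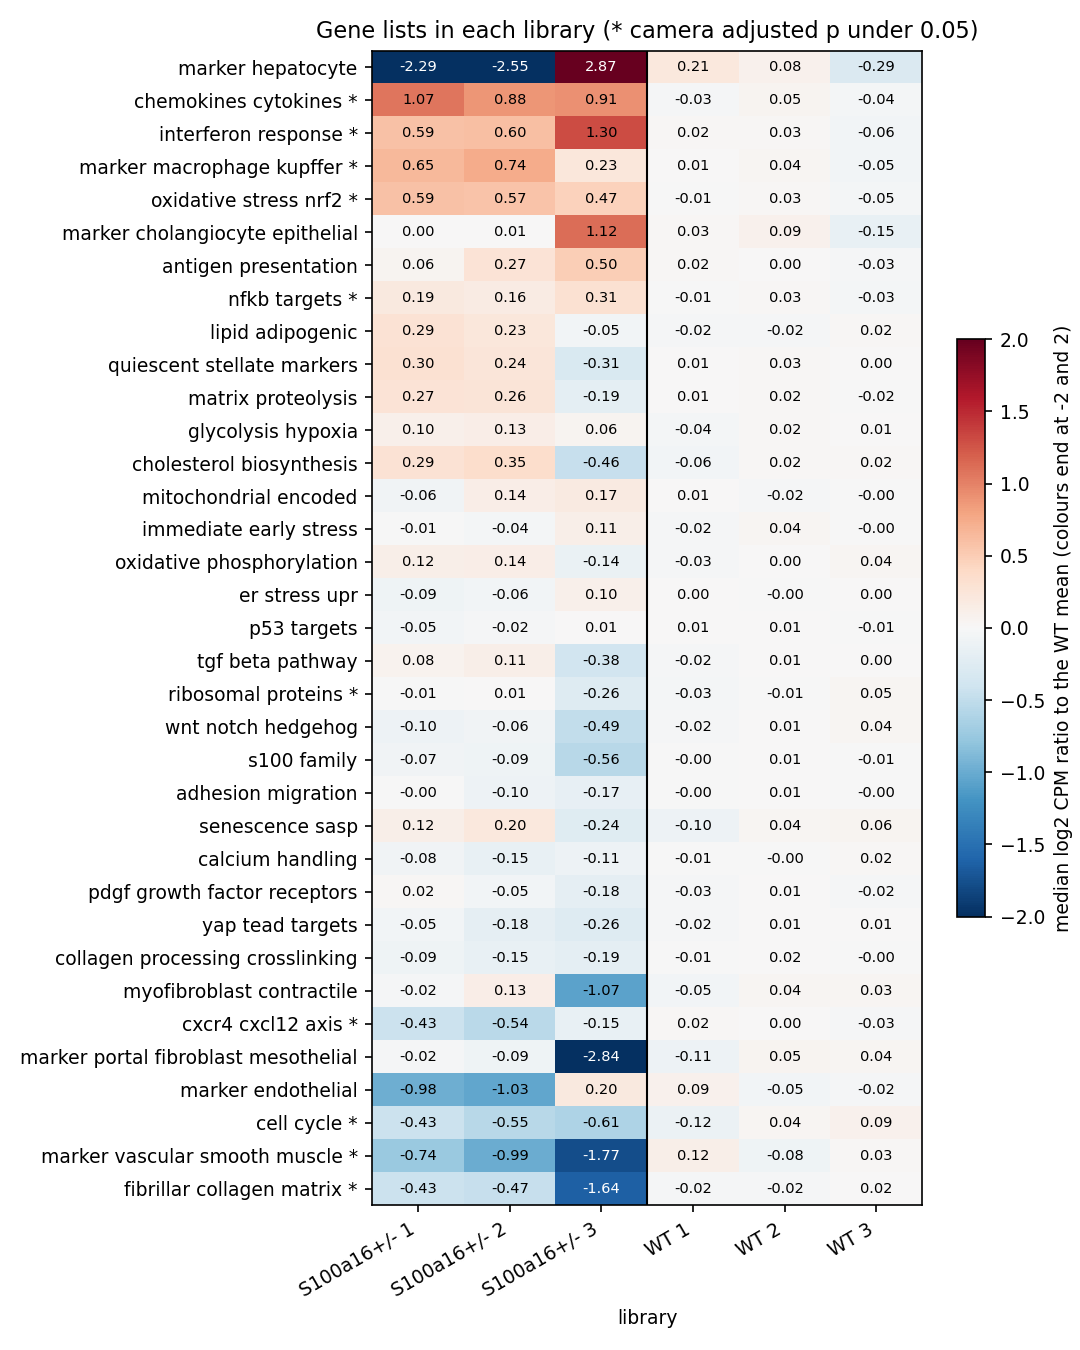
Median log2 ratio of CPM to the WT mean for 35 gene lists (vertical axis) in each of the 6 libraries (horizontal axis), with colours ending at ±2 and a star where the camera adjusted p was under 0.05. Chemokines are above 0 and the cell cycle below 0 in all 3 S100a16+/- libraries, while the hepatocyte markers stand at -2.29 and -2.55 in replicates 1 and 2 and at 2.87 in replicate 3.

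Markers of other liver cells differed between the S100a16+/- libraries. The endothelial median was -0.98 and -1.03 in S100a16+/- replicates 1 and 2 and 0.20 in replicate 3 (camera adjusted p = 0.0575; 0.0259 with the replicate number as a block; adjusted p = 0.723 with an estimated correlation). Of 18 endothelial markers none passed over all 6 libraries by edgeR (1 higher and 2 lower at an unadjusted p under 0.05, 1 higher and 1 lower by DESeq2), and 1 rose adjusted over the list alone. In the fit without S100a16+/- replicate 3, 15 were lower and 1 higher (camera adjusted p = 6.32e-07; adjusted p = 0.473 with an estimated correlation), and the vascular cadherin gene Cdh5 went from -0.36 to -1.14 (edgeR adjusted p = 0.715 and 0.000161). The hepatocyte median was -2.29, -2.55 and 2.87 in S100a16+/- replicates 1 to 3. Of 14 hepatocyte markers none passed, also adjusted over the list alone (1 higher at an unadjusted p under 0.05 and 1 by DESeq2; camera adjusted p = 0.916), and without replicate 3, 11 of 13 were lower and 2 higher (camera adjusted p = 0.00117; adjusted p = 0.528 with an estimated correlation). Vascular smooth-muscle markers were lower as a list (camera adjusted p = 0.0228; adjusted p = 0.332 with an estimated correlation), with 1 of 9 called, Notch3 at -1.62 (edgeR adjusted p = 0.0419), and 2 adjusted over the list alone. Its median was -0.74, -0.99 and -1.77 in S100a16+/- replicates 1 to 3, 6 were lower and 1 higher without replicate 3 (camera adjusted p = 0.0462; adjusted p = 0.545 with an estimated correlation), and the list was not called without WT replicate 1, 2 or 3 (camera adjusted p = 0.212, 0.161 and 0.166) or among genes with a mean FPKM of at least 5 (camera adjusted p = 0.187). Portal fibroblast and mesothelial markers had medians of -0.02, -0.09 and -2.84, with Eln the 1 member of 11 that fell, 2 adjusted over the list alone (camera adjusted p = 0.0569; 0.0116 and 0.0185 without S100a16+/- replicate 1 or 2, and 0.0386 with the replicate number as a block; adjusted p = 0.587 over all 6 with an estimated correlation). That list was not called without S100a16+/- replicate 3, where its median was 0.0079 (camera adjusted p = 0.332). Among cholangiocyte and epithelial markers Spp1 was the 1 of 6 that rose, and 1 adjusted over the list alone (camera adjusted p = 0.335). With S100a16+/- replicate 3 left out, 1 of the portal and mesothelial markers was higher and 4 lower, 1 cholangiocyte marker and 3 neutrophil markers were higher, and 2 lymphocyte markers were lower. Of 4 neutrophil markers tested 2 rose, S100a8 and Mmp9, and 3 adjusted over the list alone. Of 4 lymphocyte markers none passed, also adjusted over the list alone and at an unadjusted p under 0.05 by edgeR or by DESeq2, and no erythroid gene reached the expression minimum.

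Of 1908 GO terms 34 were higher and 36 lower by camera, among them phagocytic vesicle membrane, higher (adjusted p = 5.67e-06), defense response to bacterium, higher (adjusted p = 1.10e-05), cellular response to interferon-beta, higher (adjusted p = 7.67e-05), condensed chromosome kinetochore, lower (adjusted p = 0.000385), and basement membrane, lower (adjusted p = 0.00154). Each of these GO terms had an adjusted p = 0.772 with an estimated correlation. Of 276 KEGG pathways 17 were higher and 7 lower, led by lysosome (adjusted p = 1.78e-05), ferroptosis (adjusted p = 0.000151) and phagosome (adjusted p = 0.000173) on the higher side and spliceosome (adjusted p = 0.00154) on the lower. These 4 pathways had an adjusted p = 0.491 with an estimated correlation. In the same S100a16+/- replicates 1 to 3 the macrophage markers had medians of 0.65, 0.74 and 0.23 and the endothelial markers of -0.98, -1.03 and 0.20. Without S100a16+/- replicate 3, 18 GO terms were higher and 14 lower, and 16 KEGG pathways were higher and 3 lower, by the preset correlation. With an estimated correlation no list, GO term or KEGG pathway passed in camera over all 6 libraries, where an unadjusted p under 0.05 gave 3 higher and 2 lower of 35 lists, 56 and 43 GO terms and 17 and 5 pathways. The other set test, fry, which asks only whether a list's genes move on balance in a single direction, put 5 lists higher and 8 lower.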

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

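The DESeq2 fit, library totals without TMM and camera on counts were chosen after the data were seen, and the other alternatives before. The limma fit was the planned test for FPKM alone and became an alternative once counts were found. Since all called genes had non-overlapping groups, leaving out a library could hardly reverse their direction, so the next count is no sign of strength. Of the 72 called named genes, S100a16 is treated on its own, and the 71 others reversed in no alternative in which they were tested. That was 55 of them with a mean FPKM of at least 5, 69 with an S100a16+/- library left out, 66 with a WT library left out and all 71 elsewhere. The 71 stayed past the threshold with DESeq2 and with array weights. Of them 23 lost their call with no filter, 12 with quantile normalization, and 9 and 8 with pseudocounts of 0.1 and 5. TPM and limma with or without trend each lost 7, and the replicate number as a block lost all 71. Leaving out S100a16+/- replicate 1 or 2 lost 48 and 52 of 69, and leaving out WT replicates 1, 2 or 3 lost 55, 55 and 56 of 66. The samples share only a number: deviations of same-numbered libraries correlated at -0.14, 0.04 and -0.05, only S100a16+/- replicate 2 correlated best with its own number, which is a hint from the data and not the design. With the replicate number as a block, 0 genes were higher and 0 lower by edgeR (1233 and 974 at an unadjusted p under 0.05), S100a16 stood at -1.39 (adjusted p = 0.139), Alb at -2.04 and Timp1 at -0.23, and the senescence list was on the lower side (camera adjusted p = 0.833). The endothelial and the portal and mesothelial lists, not called over all 6 libraries, passed on the lower side with the block (camera adjusted p = 0.0259 and 0.0386). No other tool was run with the block. What depth limits was not measured by expression level: the self-test recovered 47% of genes changed 2-fold with all 6 libraries and 80% without S100a16+/- replicate 3.

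The counts of genes, 364 higher and 206 lower, moved to 162 and 81 with no filter on low values, where more genes are tested. They moved to 1718 and 2831 with array weights, where S100a16+/- replicate 3 has a weight of 0.0981, to 1125 and 763 with DESeq2, to 772 and 466 at an adjusted p under 0.1, to 74 and 25 with a change of at least 1 in log2(FPKM + 1), and to 139 and 69 with that change at an unadjusted p under 0.05. TPM gave 228 higher, and a mean FPKM of at least 5 gave 137 lower. With each library left out in turn the counts ran from 20 to 1990 higher and from 5 to 2076 lower. The common dispersion was 0.0600 over all 6 libraries and 0.0214 without S100a16+/- replicate 3. Without S100a16+/- replicates 1 or 2 it was 0.0585 and 0.0572, and there fewer genes were called than over all 6. The cause of the differences in the counts was not tested.

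S100a16 was -1.36 with no filter on low values (adjusted p = 0.0516) and ran from -1.63 to -1.22 with libraries left out. Cxcr4 was -1.92 with array weights (adjusted p = 0.00106, against 0.0832 to 0.384 over the other alternatives with all 6 libraries) and ran from -1.95 to -0.86 with libraries left out. Alb, at 0.64 in edgeR, was -1.53 and -1.01 with pseudocounts of 0.1 and 5, -1.54 with TPM, -1.34 with quantile normalization, -1.40 with limma with or without trend and -3.03 with array weights, and ran from -3.35 to 1.20 with libraries left out. Timp1 was -0.31 and -0.27 with those pseudocounts, -0.00229 with no filter, -0.00260 with a mean FPKM of at least 5, -0.35 with TPM, -0.31 with quantile normalization, -0.30 with limma with or without trend and -0.059 without TMM, and ran from -0.28 to 0.43. With array weights Krt18 was -0.30, Csf3r -0.063 and Acta2 0.11. With libraries left out Krt18 ran from -0.31 to 0.80, Gas6 from -0.53 to 0.024, Csf3r from -0.0064 to 0.21, Acta2 from -0.62 to 0.27 and Col1a1 from -0.89 to 0.0013. In each of these ranges S100a16+/- replicate 3 gave an end. The cause was not tested.

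Of the lists, 9 were higher and 10 lower with no filter, 9 higher with array weights, 3 lower with a mean FPKM of at least 5, and 8 lower with median-of-ratios scaling, quantile normalization, camera on counts or fry. With an estimated correlation 0 lists, GO terms and KEGG pathways were higher and 0 lower (at an unadjusted p under 0.05, 3 higher and 2 lower of 35 lists). With libraries left out 5 to 9 lists were higher and 4 to 8 lower. GO terms gave 64 higher and 78 lower with no filter, 22 and 13 with array weights, 20 higher with ranks and 22 lower with a mean FPKM of at least 5, and 18 to 39 higher and 14 to 40 lower with libraries left out. KEGG pathways gave 9 higher with quantile normalization or ranks, 3 lower with a mean FPKM of at least 5, 4 lower with median-of-ratios scaling or camera on counts, 2 lower with array weights, and 3 to 8 lower with libraries left out. The cause was not tested.

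Lists outside the called ones changed side in some settings, and their camera or fry adjusted p there is given next. The TGF-beta list had 0.788 with array weights. The senescence list had 0.866 with no filter, 0.944 with median-of-ratios scaling, 0.992 with TPM, 0.866 with quantile normalization, 0.868 with camera on counts and 0.793 with fry. Cholesterol synthesis had 0.983 with fry, and oxidative phosphorylation 0.959 with TPM, 0.922 with quantile normalization and 0.967 with fry. The ER stress list had 0.944 with median-of-ratios scaling and 0.969 with camera on counts, and the immediate early list 0.878 with no filter and 0.672 with fry. Antigen presentation had 0.960 with quantile normalization, 0.868 with camera on counts and 0.0103 with fry, which passed on the lower side. Hepatocyte markers had 0.859 with a pseudocount of 0.1, 0.828 with median-of-ratios scaling, 0.892 with quantile normalization, 0.0555 with array weights, 0.969 with camera on counts and 0.967 with fry. Mitochondrial transcripts had 0.702 with quantile normalization, 0.899 with array weights and 0.769 with fry. With libraries left out the adjusted p ran from 0.00659 to 0.468 for contractile genes, 0.175 to 0.504 for TGF-beta, 0.468 to 0.967 for senescence, 0.000149 to 0.987 for cholesterol synthesis, 0.0126 to 0.987 for oxidative phosphorylation, 0.217 to 0.967 for ER stress and 0.00117 to 0.967 for hepatocyte markers. Lists not called over all 6 libraries that passed in other settings kept their side without a call in 12 of 20 settings for contractile genes and oxidative phosphorylation, and in 13 for endothelial and for hepatocyte markers. The number was 14 for portal and mesothelial markers and for cholesterol synthesis, 15 for matrix proteases and for lipid genes, and 17 for collagen processing, YAP targets and antigen presentation. It was 19 for Wnt, Notch and Hedgehog and for calcium handling, and 18 of 19 for cholangiocyte markers. The cause was not tested.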

Other observations

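The tests of a smaller stellate share, a larger macrophage share and fewer endothelial cells were given a further bound after the values were seen, and those of a wrong label and of fewer macrophages were chosen after the result was seen; the others were set before. Of 22 genes of the response to oxidative stress through the transcription factor NRF2, 5 rose, against 9 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000700; adjusted p = 0.320 with an estimated correlation). The heme oxygenase gene Hmox1 rose by a log2 change of 1.04, Srxn1 by 1.06 and Gsta3 by 0.98 (edgeR adjusted p = 0.0340, 0.0292 and 0.0382). The list's median was 0.59, 0.57 and 0.47 in S100a16+/- replicates 1 to 3, where the macrophage markers had 0.65, 0.74 and 0.23, and without replicate 3, 13 members were higher and 5 lower (camera adjusted p = 0.00154; adjusted p = 0.439 with an estimated correlation). Among glycolysis and hypoxia genes 4 of 29 rose, against 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0755): the hexokinase genes Hk2 at 0.45 and Hk1 at 0.27, Pfkp at 0.73 and the glucose transporter gene Slc2a1 at 0.35 (edgeR adjusted p = 0.0218, 0.0474, 0.0313 and 0.0479), while without S100a16+/- replicate 3, 12 were higher and 5 lower. Of 23 lipid genes 1 rose, the fatty acid carrier gene Fabp5 at 1.23 (edgeR adjusted p = 0.00211), also adjusted over the list alone (camera adjusted p = 0.0831; 0.00595 without S100a16+/- replicate 3 and 0.0442 without WT replicate 3). With an estimated correlation the adjusted p = 0.659 over all 6 libraries and 0.439 without S100a16+/- replicate 3, where 10 were higher and 2 lower. None of 23 cholesterol-synthesis genes passed by edgeR, also adjusted over the list alone (1 lower at an unadjusted p under 0.05 and 1 by DESeq2; camera adjusted p = 0.735), while without S100a16+/- replicate 3, 14 were higher and 1 lower (camera adjusted p = 0.000149; adjusted p = 0.458 with an estimated correlation). Ribosomal protein genes were lower as a list by a median of -0.08 (camera adjusted p = 0.00437; adjusted p = 0.723 with an estimated correlation; 0.221 without S100a16+/- replicate 3), with none of 36 called by edgeR, also adjusted over the list alone (2 lower at an unadjusted p under 0.05, 1 by DESeq2), and 1 higher and 1 lower without S100a16+/- replicate 3.

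Of 29 TGF-beta genes 1 fell, Smad3 at -0.37 (edgeR adjusted p = 0.0251), against 2 adjusted over the list alone (camera adjusted p = 0.463), and Tgfb1 was at 0.22 (edgeR adjusted p = 0.442). Leaving out S100a16+/- replicate 3 gave 11 higher and 11 lower TGF-beta genes, and Tgfb1 passed at 0.36 (edgeR adjusted p = 0.00269). Of 24 growth factor and receptor genes 2 fell, Pdgfc at -0.92 and Hbegf at -0.36 (edgeR adjusted p = 0.0120 and 0.0449), against 3 adjusted over the list alone (camera adjusted p = 0.415), and Pdgfrb was at -0.46 (edgeR adjusted p = 0.541). Leaving out that library gave 6 higher and 7 lower growth factor genes, with Pdgfrb at -0.13 (edgeR adjusted p = 0.563). In the S100 family of 9 tested genes S100a10 fell by 0.55 (edgeR adjusted p = 0.0104) beside S100a16, while S100a8 rose, with the same 3 adjusted over the list alone (camera adjusted p = 0.385), and 2 higher and 3 lower without that library. Other lists with a called gene were immediate early (Nr4a1 at -0.87, of 27; list alone 3 higher, 1 lower), YAP targets (Dlc1 at 0.37, of 18; 1 and 1), Wnt, Notch and Hedgehog (Sfrp1 at -0.41 and Notch3, of 17; 2 and 2), adhesion (Cdh6 at 2.31, of 26; 1 and 1) and ER stress (Asns at 0.45, of 28; none). Their camera adjusted p were 0.662, 0.124, 0.546, 0.538 and 0.921, and YAP targets had 0.0460 without S100a16+/- replicate 1 (adjusted p = 0.391 over all 6 with an estimated correlation). Without S100a16+/- replicate 3, 5 immediate early genes were higher and 6 lower, 3 and 5 YAP targets, 4 and 4 Wnt, Notch and Hedgehog genes, 7 and 8 of 24 adhesion genes, and 6 and 8 ER stress genes. Lists with no called gene by edgeR were collagen processing (22 tested, camera adjusted p = 0.125, 1 higher and 4 lower at an unadjusted p under 0.05 and also by DESeq2), quiescent stellate markers (11, 0.643, 1 and 1 by both), senescence (12, 0.954, 3 and 1 by both), calcium handling (18, 0.125, 1 and 4, and 1 and 1 by DESeq2), oxidative phosphorylation (35, 0.662, 1 higher by both) and mitochondrial transcripts (15, 0.662, 2 and 1, and 1 and 1 by DESeq2). Adjusted over the list alone, 2 senescence genes were higher and 1 lower, and none passed in the other 5 of these lists. With S100a16+/- replicate 3 left out, 1 collagen processing gene was higher and 7 lower, 5 and 2 quiescent markers, 5 and 2 senescence genes, 2 and 5 calcium genes, 1 and 2 mitochondrial transcripts, and 7 oxidative phosphorylation genes were higher. In that setting camera called collagen processing lower and oxidative phosphorylation higher (adjusted p = 0.0309 and 0.0126; adjusted p = 0.458 and 0.615 with an estimated correlation). Median, mean and test differed in sign for senescence (-0.12, -0.12, higher), the S100 family (-0.11, 0.15, lower) and ER stress (0.00, 0.05, lower).

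S100a16+/- replicate 3 stood apart from the other 5 libraries. Against S100a16+/- replicates 1 and 2 its contractile and matrix genes had a median of -0.99, on the side of a smaller share of stellate-derived cells. Its hepatocyte, endothelial and macrophage medians were 5.22, 1.22 and -0.43, a distance of 5.65 against a largest SD over members of 3.00. Such a smaller share would raise these alike only if the mix of the other cells stayed the same, which was not measured. The test therefore cannot decide, and its bound on the distance was added after the values were seen. A loss of depth or complexity is argued against by 22598 genes with a count after thinning to a common total, within the 22594 to 23176 of the others, and a WT library under the wrong label by an S100a16 FPKM of 30.0, below the lowest WT value of 56.8. Its Xist FPKM of 32.2, against at most 0.0323 in the others, shows that it came from another animal than the other 5 libraries. Whether that animal or another cell mixture underlies the difference stays open, and what part the sex of the animal has in it was not tested. No biological explanation beyond the share of stellate-derived cells was tested, because the design gives none within a genotype.

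Macrophage markers had a median of 0.69 without S100a16+/- replicate 3, with 15 higher and 5 lower. The bound that decides on a larger share of macrophages as the only cause was added after the values were seen. Without it, the median and the share of markers that were higher would leave this open. By that bound it is argued against by the markers that went the other way: 5 of the 20 called, 25%, were lower. These were named after their values were seen: Mrc1, C1qa, C1qb, C1qc and Timd4. A changed state of the macrophages, a change in share beside it, and genotype stay open and untested, and 72% of the 25 markers were higher. All 25 listed markers passed the expression minimum in these cultures, and no marker of this list is in another list.

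Cxcr4 was lower in the S100a16+/- libraries, mainly in replicates 1 and 2. Fewer macrophages as a whole are argued against as a cause by their higher markers, with a median of 0.69 without S100a16+/- replicate 3. A loss of only some of the macrophages stays open, since 5 of their 20 called markers were lower without S100a16+/- replicate 3. Fewer endothelial cells may be part of it: without that library the endothelial median was -1.01, just past 0.5 of the Cxcr4 change, with 1 of 16 called markers the other way, and in replicate 3, where Cxcr4 stood at 80.9% of WT, the endothelial median was 0.20. Of the most abundant endothelial genes Cdh5 was at -1.14 and Eng at 0.09 without replicate 3 (edgeR adjusted p = 0.000161 and 0.297), and 18 of the 21 listed markers passed the expression minimum, with none in another list. Genotype within the stellate cells or the macrophages stays open, since the share of cells was not measured.

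Splits of the 6 libraries are too few for a share under 0.05: 1 of the 10 splits, the real one with 570 calls, gave as many genes, and the highest of the others gave 3. Within 10 Mb of S100a16, 11 of 206 other genes (5.34%) were called against 558 of 12559 elsewhere (4.44%; Fisher's exact test, two-sided, p = 0.495). Without S100a16+/- replicate 3 these were 67 of 203 (33.0%) and 3998 of 12397 (32.2%; the same Fisher's exact test, two-sided, p = 0.821). The nearby share was neither clearly above nor at or below the share elsewhere. The 11 nearby calls include S100a8, at 0.13 Mb from S100a16, and S100a10, at 3.02 Mb. Sequence carried along with the targeted allele cannot be told apart from genotype here, because it would go with the genotype in each library.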
